A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

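Messenger RNA of 4 fission yeast (Schizosaccharomyces pombe) samples was measured on Affymetrix arrays. The cells were h+/h- diploids of 2 genotypes, wild type and a deletion of pht1, the gene of the histone variant H2A.Z. Each genotype was sampled 1.5 h and 3 h after nitrogen was withdrawn to induce meiosis. The sample titles do not say whether both times of a genotype came from 1 culture. Per the labels' protocols, total RNA was treated with DNase, poly(A) RNA was purified from it, and biotin-labelled cRNA was made for hybridization. The 4 groups hold 1 array each, so no group has a replicate.

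The deposited table holds 1 log2 value per probe set and array, made by RMA per the submitters' processing notes. RMA corrects the background, equalizes the distributions between arrays and summarises the probes of a set. Its version and the set of arrays normalized together are not given in the sources used here. Equalized distributions remove any difference in total mRNA between the cultures, so each value is relative to the other transcripts of its array. The array medians were 11.27 and 11.24 for wild type at 1.5 h and 3 h, and 11.26 and 11.23 for the deletion. The table held 4999 probe sets. Of these, 2917 had 1 gene symbol in the platform annotation, 20 had several and 2062 were unnamed here. Of the named probe sets, 2914 matched by gene identifier to a RefSeq gene table of assembly ASM294v3, used for names and neighbours alone, and 112 symbols were updated. This gave 2899 genes. For the 14 genes with several probe sets, the set with the highest mean was taken.

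Differences are log2 values of 1 array minus 1 array. Genes were counted at a 2-fold difference (1 log2 unit) when the higher array of the comparison lay above a floor. The plan set the floor from probe sets of S. cerevisiae if the table had them, and otherwise at the 25th percentile of each array. No such probe sets were in the table used here, so the floors were 10.12 and 10.13 for wild type at 1.5 h and 3 h, and 10.10 and 10.08 for the deletion. Single-array differences have no replicate check and carry no p-value.

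For 31 gene lists, the median difference was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list with at least 5 members above the floor stood apart when its percentile was under 2.5 or over 97.5. The percentile describes these arrays and not repeated cultures. For 4 genes, a match to a list through an older name was left out because the name belongs to another gene. The Tf2 retrotransposon list had 0 probe sets with a single symbol and was not analysed.

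A difference common to both times was tested with limma 3.58.1 in R 4.3.3, fitting genotype and time as additive terms on the 2314 genes above the floor on at least 2 arrays, with moderated variances that follow intensity and Benjamini-Hochberg adjustment at 0.05. This fit has 1 residual degree of freedom per gene, which holds array noise and any interaction of genotype with time. Its p-values measure the spread between these 4 arrays and not between cultures. Simulated arrays with the real means and time effects were used to test the steps. Each gene took the noise size of a random gene, drawn independently on each array. The simulation thus held no interaction, no link of noise to intensity and no genes moving together, so it does not cover lists of co-regulated genes. In 2314 simulated genes, the additive fit called 74.0% of those changed by 1 log2 unit, 87.0% of those changed by 2 units and 0.236% of the 2114 unchanged genes. A single-array comparison put 48.0%, 99.0% and 0.804% of the same classes at 2-fold or more. Of 100 unchanged simulated lists of 15 genes, 6 stood apart, and so did all 100 lists shifted by 0.3.

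Most genes named here follow a rule set before the data were examined. It takes pht1 and ura4, all measured members of the double-strand break list, the 10 highest and 10 lowest genes of each genotype comparison, and the 5 highest and 5 lowest of each time comparison and of the difference of differences. It adds the list members with the largest differences and the 5 genes with the largest difference each way in the additive fit. Neighbours of pht1, some genes that differed at both times and some genes of the closing parts were named beyond this rule. Alternatives covered scaling, the floor, the choice of probe sets, the fold threshold and the variance model. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.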

Results

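Transcript levels of wild-type and pht1-deleted diploids were compared early in meiosis, at 1.5 h and 3 h after nitrogen withdrawal, with 1 array for each of the 4 combinations. The title of the series concerns H2A.Z in the initiation of meiotic recombination, so the genes for double-strand break formation are reported in full. The number of arrays limits the precision, and the single-array differences below have no replicate check. Over the genes above the floor, the spread of a difference between 2 arrays, estimated from the difference of differences, was 0.23 log2 units.

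The pht1 probe set read 12.70 and 12.86 on the wild-type arrays at 1.5 h and 3 h, and 7.37 and 7.36 on the deletion arrays, a difference of -5.32 and -5.50. These deletion values lay at the 0.660 and 0.640 percentiles of their arrays. The ura4 probe set, which reads a common selection marker, was 12.70 and 12.38 in wild type and 12.00 and 11.89 in the deletion. Of the 9 measured genes within 5 positions of pht1, the nearest were cdc2 (0.073 and 0.055) and shy1 (-0.30 and -0.24), and those with the largest differences were rsp1 (0.49 and 0.17), tas3 (-0.49 and -0.22) and sws1 (0.44 and 0.13).

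At 1.5 h, the 10 highest genes in the deletion all belonged to a list of meiotic genes, ght6 through a meu synonym. The spore wall gene isp3 was higher by 6.06 log2 units, meu17 by 4.88, spo5 (a meiotic RNA-binding protein) by 4.33, meu31 by 4.20 and meu7 by 4.02. They were followed by mde5 (3.79), meu6 (3.77), meu10 (3.69), meu15 (3.18) and the hexose transporter gene ght6 (3.12). In wild type, isp3, meu17, meu31, mde5, meu6, meu10, meu15 and ght6 read under 8.37, a level 1 log2 unit above the deleted pht1 that was set after seeing the data, so these 8 differences are lower bounds and their order is not settled. After pht1, the lowest were usp109 of the U1 snRNP (-1.58), the phosphatidylinositol phosphate kinase gene its3 (-1.43), coq8 of ubiquinone synthesis (-1.41), adh4 (-1.37), coa1 (-1.28), the SAGA subunit gene sgf73 (-1.26), dph4 (-1.25), the remodeller subunit gene arp9 (-1.25) and ypt4 (-1.20). In all, 60 of 2331 genes above the floor were at least 2-fold higher and 21 at least 2-fold lower. A 3-fold difference was reached by 32 genes on the higher side and by pht1 alone on the lower side.

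Mating pheromone genes were higher in the deletion at 1.5 h without exception among the 22 measured. Their median was 0.97 and 9 were at least 2-fold higher, led by the M-factor receptor gene map3 (2.83), the P-factor gene map2 (2.42), the carboxypeptidase gene sxa2 (2.25) and map4 (2.18). Of the 15 middle meiosis genes above the floor, 14 were higher and 9 at least 2-fold, with a median of 1.36 and crs1, a meiotic cyclin gene, at 2.66. The lists of Mmi1-regulated transcripts (median 1.18 over all 19 genes without the floor) and of genes named meu (median 3.18 over 15 above it and 1.45 over all 28) shared members with it. Late meiosis and spore wall genes had a median of 0.80 over 13, with ght3 at 1.43, mde10 at 1.27 and mok14 at 1.23. Among 7 regulators of meiotic entry, with a median of 0.64, the kinase gene pat1 was at 1.37, the activator gene rep1 at 1.35, the transcription factor gene ste11 at 0.99 and mei2 at 0.64. Genes of strand exchange had a median of 0.44 over 18, with meu13 at 1.96, rti1 at 1.72 and the recombinase gene dmc1 at 1.38. Each of these lists stood above the upper bound of its random lists. With a stricter floor at the array median, strand exchange and Mmi1 kept 4 genes each and no percentile, and the middle meiosis median was 3.69 over 7.

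Double-strand break genes were mostly dim at 1.5 h, and 4 of the 13 lay above the floor, too few for a percentile. The linear element and checkpoint genes hop1 (2.02) and mek1 (1.32) were higher in the deletion, and rec6 (0.36) and rec14 (-0.19) differed less. Below the floor, rec15 (1.37), rec10 (1.32), mug20 (1.17), rec25 (1.06), mde2 (0.84) and rec27 (0.59) were also higher. Those of rec15, rec10, rec25 and mde2 are lower bounds with no settled order, since wild type read under 8.37, and rec27, rec24 and rec7 read under it in both genotypes, so their differences are not settled. The gene of the break-forming Spo11 homologue, rec12, differed by 0.01, rec24 by 0.05 and rec7 by 0.00. Without the floor, 12 of the 13 were higher by some amount, with a median of 0.84 at percentile 100 of the matched lists.

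Core histone genes were lower in the deletion at 1.5 h in all 9 cases above the floor, with a median of -0.31 at percentile 0. The H4 gene hhf1 (-0.73) and the H3 gene hht1 (-0.57) had the largest differences, and hhf3 was at -0.38. Iron, copper, zinc and phosphate uptake genes had a median of -0.21 over 17, with sib2 at -0.89 and vht1 at -0.75, while 7 were higher, among them zym1, a metallothionein gene, by 1.08 and ctr4 by 0.85. Nitrogen starvation genes also stood below (median -0.14 over 18), but the largest differences were those of isp3 (6.06), ste11 (0.99) and uga1 (0.84), among 7 higher, and then car1 (-0.82) and isp5 (-0.72). With the stricter floor both lists moved inside the random range, metal and phosphate at -0.080 (percentile 18.2) and nitrogen starvation at -0.10 (percentile 7.35), as did nitrogen starvation after quantile normalization (percentile 2.78). Cytosolic ribosomal protein genes stood below with a median of -0.033 over 111, or -0.010 after lowess, although 32 were higher, led by rps1401 (0.51) and rpl3002 (0.43), and rpl502 was at -0.33. The telomere bouquet list had a median of 0.27 over 8, with 6 higher, num1 at 2.005 or more, dlc1 at -0.45 and taz1 at 0.41, and kept 4 genes and no percentile with the stricter floor. Smaller positive shifts were those of the mug genes (0.23 over 85, mug14 at 2.61), ribosome biogenesis (0.18 over 16, gar2 at 1.05 and ebp2 at 0.57), stress response (0.10 over 23, ctt1 at 0.86) and heat shock (0.09 over 15, mas5 at 0.34). Of 28 lists with a percentile, 13 stood above and 5 below their random lists. Independent lists of unrelated genes would give 1.40 in all, but these lists share members and their genes can move together. The remaining list below was that of the strain marker loci, which holds pht1 itself.

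At 3 h, 9 of the 10 highest genes belonged to a list of meiotic genes, all but pma2. They were meu17 (5.26), mde5 (4.65), meu31 (4.40), meu7 (4.26), meu6 (4.02), ght6 (3.85) and meu15 (3.70), then the proton pump gene pma2 (3.33), meu14 (3.30) and mug97 (3.26). The differences of meu17, mde5, ght6, meu15, pma2, meu14 and mug97 are lower bounds with no settled order, since wild type again read under 8.37 for them. After pht1, the lowest were usp109 (-1.51), the copper transporter gene ctr4 (-1.42), ypt4 (-1.42), sgf73 (-1.33), omt2 (-1.30), the SWR1 subunit gene swc5 (-1.28), coa1 (-1.23), its3 (-1.20) and the uracil permease gene fur4 (-1.20). Of the 44 genes at least 2-fold higher, 11 had a wild-type value under that level, as had 11 of the 60 at 1.5 h. At least 2-fold differences were found for 44 higher and 20 lower genes of 2337.

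Middle meiosis genes kept a high median at 3 h, 1.19 over 19 genes with 12 at least 2-fold higher, including spo6 (at least 3.13, from a wild-type value under 8.37) and the meiotic septin gene spn5 (2.23). The members above the floor differ between the times. Over all 28 without the floor, the median was 0.98 at 1.5 h and 1.26 at 3 h. The meu genes had a median of 2.94 over 20 and 1.69 over all 28 without the floor, and the late meiosis and spore wall list 0.82 over 14, with the glucanase gene agn2 at 2.12 and mok14 at 1.82. The pheromone list had a median of 0.14, with 16 of 22 genes higher, map3 at 1.66 and map4 at 1.11. Meiotic entry genes (0.17 over 8, the forkhead gene mei4 at 1.12), strand exchange genes (0.19 over 18 and 0.11 over all 23, exo1 at 0.65) and Mmi1-regulated transcripts (0.35 over 14, meu10 at 1.92) were also above their random lists. With the stricter floor these 3 lists moved inside the random range, at percentiles 93.9, 85.6 and 94.4. Of the double-strand break genes, mde2 was higher by 2.18, rec15 by 0.63, mug20 by 0.55, hop1 by 0.41, rec27 by 0.38, rec25 by 0.29, mek1 by 0.23 and rec10 by 0.20. The others were rec24 (0.08), rec14 (-0.03), rec6 (-0.05), rec12 (-0.06) and rec7 (-0.14). The 9 above the floor had a median of 0.29 at percentile 95.8, inside the range of random lists, and all 13 had a median of 0.23 at percentile 99.4 without the floor.

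Core histone genes had a median of 0.02 at 3 h, inside the range of random lists, with cnp1, the centromeric H3 gene, at 0.26. Ribosome biogenesis (0.29 over 15, utp15 at 0.40), mug genes (0.24 over 103, mug137 at 3.24 or more), stress response (0.14 over 23, zym1 at 1.76 and atf1 at 0.78), S phase genes (0.14 over 22, 0.082 over all 28 and 0.25 over 13 with the stricter floor, mik1 at 0.59, cdc18 at 0.50 and mcm7 at -0.43) and metal and phosphate uptake (0.12 over 17, with zym1 again and ctr4 at -1.42) stood above their random lists. The list of other chromatin factors stood below (-0.18 over 22, vid21 at -0.48 and set2 at -0.47), but moved inside with the stricter floor, at -0.032 over 9 genes and percentile 33.4. In the SWR1 complex, which deposits H2A.Z, swc5 was at -1.09 and -1.28 at 1.5 h and 3 h and alp5 at -0.41 and -0.43, while the list as a whole lay inside the random range at both times. Of 29 lists, 13 stood above and 1 below, where independent lists of unrelated genes would give 1.45, which these lists are not.

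**Figure D1:**
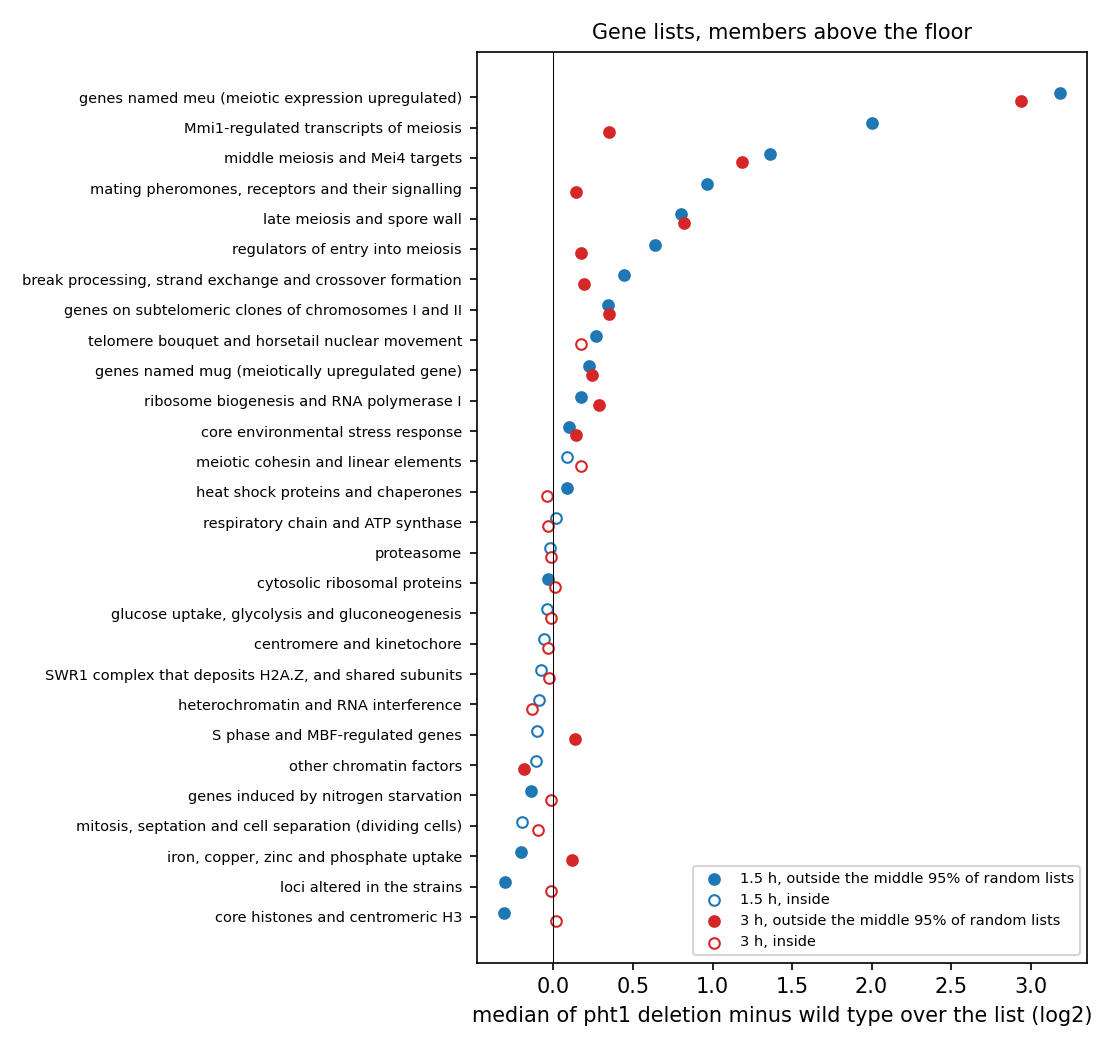
Median log2 difference between the pht1 deletion and wild type for each of 28 gene lists, over members above the floor, at 1.5 h (blue) and 3 h (red). Filled points lie outside the middle 95% of matched random lists. The pheromone list goes from 0.97 at 1.5 h to 0.14 at 3 h. The middle meiosis list stays above 1 over its 15 members above the floor at 1.5 h and 19 at 3 h.

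Meiotic cohesin and linear element genes had medians of 0.09 over 7 genes at 1.5 h and 0.17 over 14 at 3 h, inside the random range, with hop1 at 2.02 and psc3 at -0.50 at 1.5 h. Without the floor, the medians of all 16 were 0.51 and 0.23, above the random range, with rec11 at 1.89 or more and rec8 at 1.60 at 1.5 h. Lists inside the random range at both times were kinetochore (-0.06 and -0.03, with mis14 at -0.74 and -1.14 and scm3 at 1.11 and 0.0075), heterochromatin (-0.09 and -0.14, with raf2 at -0.28 and -0.38), mitosis and septation (-0.20 and -0.10, with mid1 at -1.09 and -1.15), glycolysis and glucose uptake (-0.04 and -0.01), respiration (0.01 and -0.04, with sdh2 at 1.00 and -0.27) and the proteasome (-0.02 and -0.01, with rpn1302 at -0.37 and -0.33). The proteasome median at 1.5 h turned positive, 0.01, when the intensity trend was removed. Condensin had 4 genes above the floor and no percentile, with cut3 at -0.22 and -0.10.

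The differences at the 2 times, which share no array but may share cultures, overlapped. Of 2268 genes above the floor at both, 22 were at least 2-fold higher at both times, where independent lists give 0.806, and 13 were at least 2-fold lower at both, where they give 0.159. None was higher at 1 time and lower at the other by 2-fold. The genes higher at both included isp3, the meu genes meu6, meu7, meu10, meu14, meu15, meu17, meu25 and meu31, mde5, spn7, the pheromone genes map3 and map4, mel1, gal10 and zym1. Those lower at both included usp109, sgf73, arp9, swc5, iec3, its3, mid1 and pct1. Across genes, which are not independent replicates, the differences correlated with r = 0.77 and rho = 0.66, and with r = 0.76 without pht1.

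**Figure D2:**
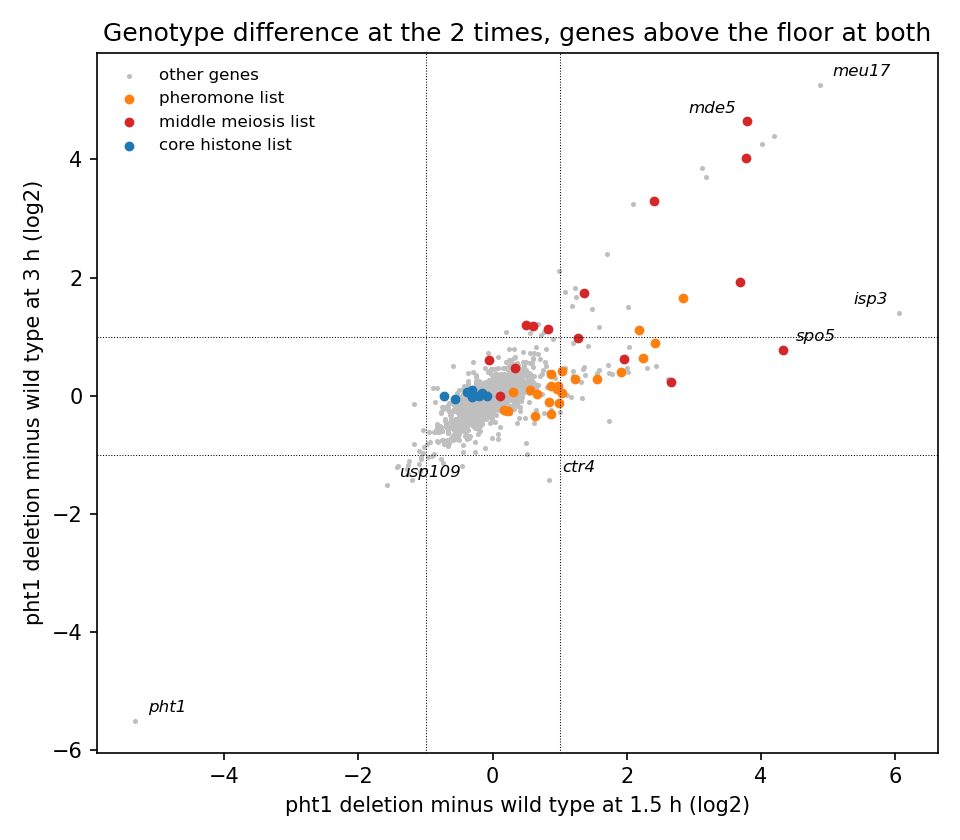
Log2 difference between the pht1 deletion and wild type at 1.5 h (horizontal) and at 3 h (vertical) for 2268 genes above the floor at both times, 1 point per gene, with dotted lines at 2-fold. Middle meiosis genes (red) such as mde5 lie high at both times, at 3.79 and 4.65, pheromone genes (orange) lie to the right, and pht1 lies at -5.32 and -5.50.

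Averaged over both times, 49 genes were called between the genotypes by limma's additive fit, 22 higher and 27 lower in the deletion. Highest were meu17 (5.07, adjusted p = 0.00208), meu31 (4.30, adjusted p = 0.00188), mde5 (4.22, adjusted p = 0.018), meu7 (4.14, adjusted p = 0.00188) and meu6 (3.89, adjusted p = 0.00295), all by limma and each higher at both times, with wild-type values under 8.37 at 1 or both times for all of these but meu7. Lowest were pht1 (-5.41, adjusted p = 0.00188), usp109 (-1.54, adjusted p = 0.018), its3 (-1.32, adjusted p = 0.0343), coq8 (-1.30, adjusted p = 0.043) and sgf73 (-1.29, adjusted p = 0.018) by limma in the same fit, each lower at both times. Of the called genes, 17 of the 22 higher ones and 1 of the 27 lower ones belonged to a list of meiotic genes. The called genes included 5 of 15 middle meiosis genes (mde10, mde5, meu14, meu6 and spn7), 8 of 16 meu genes, 3 of 10 genes on subtelomeric clones (dak2, gal10 and mel1) and, among lower genes, swc5 of the SWR1 complex. None of 8 double-strand break genes, 22 pheromone genes or 9 core histone genes was called by limma in this fit. The fit counts a difference that changes with time as residual, so it says little about these lists. Their change with time differed between the genotypes by a median of -0.74 for break genes, -0.94 for pheromone genes and 0.32 for core histones. With the stricter floor the fit called 1 gene of 1611, a higher one, so it missed the deleted pht1 itself. With the variance not following intensity it called 31 genes.

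In wild type 12 of 13 double-strand break genes and 18 of 19 Mmi1-regulated genes were higher by some amount at 3 h than at 1.5 h. The Mmi1 median was 2.86 over 13 above the floor and 1.98 over all 19. Among the highest were isp3 (5.11), spo5 (4.88), crs1 (4.14), num1 (3.52) and the meiotic cohesin gene rec8 (3.26), where the values of isp3 and num1 are lower bounds from a level under 8.37 at 1.5 h. The lowest were the ferric reductase gene frp2 (-1.74), erg32 (-1.39), adg1 (-1.36), the siderophore transporter gene str3 (-1.33) and pof14 (-1.31). Of 2330 genes, 69 were at least 2-fold higher at 3 h and 9 at least 2-fold lower. For break formation, hop1 was higher at 3 h by 3.04, rec10 by 3.00, rec15 by 2.73, mek1 by 2.65, rec25 by 2.21, mug20 by 1.91, rec27 by 1.53, rec6 by 1.33, rec12 by 0.98, mde2 by 0.90, rec24 by 0.58 and rec7 by 0.25, and rec14 was at -0.07. The wild-type values of rec10, rec15, rec25, rec27, mde2 and rec24 at 1.5 h lay under 8.37, so these are lower bounds with no settled order, and rec7 lay under it at both times. The list median was 2.43 over 8 genes above the floor and 1.53 over all 13 without it, at percentile 100 in both cases. The pheromone list had a median of 0.94 with 21 of 22 genes higher at 3 h, led by map2 (1.81), and core histones had one of -0.25, with hhf1 at -0.49.

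In the deletion all 13 break genes were higher by some amount at 3 h than at 1.5 h, 7 of the 9 above the floor by at least 2-fold. Those of rec14 and rec7 moved by less than the 0.23 spread between arrays. The highest were mde2 (2.25), rec15 (1.99), num1 (1.98), rec8 (1.92) and dmc1 (1.91), and the lowest ctr4 (-2.36), the septation gene etd1 (-1.59), ctr5 (-1.46), adg1 (-1.44) and spo12 (-1.29). Of 2329 genes, 55 were at least 2-fold higher and 11 at least 2-fold lower at 3 h. The further break genes were rec10 (1.89), mek1 (1.57), rec25 (1.45), hop1 (1.42), rec27 (1.32), mug20 (1.29), rec6 (0.92), rec12 (0.91), rec24 (0.61), rec7 (0.11) and rec14 (0.09), with rec27, rec24 and rec7 under 8.37 at 1.5 h. Pheromone genes had a median of 0.09, core histone genes 0.16 and middle meiosis genes 1.10 over 19. Of 2259 genes above the floor in both genotypes, 32 were at least 2-fold higher at 3 h in both, where independent lists give 1.08, and 3 at least 2-fold lower, where they give 0.0341. The time differences of the genotypes correlated across genes with r = 0.73.

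**Figure D3:**
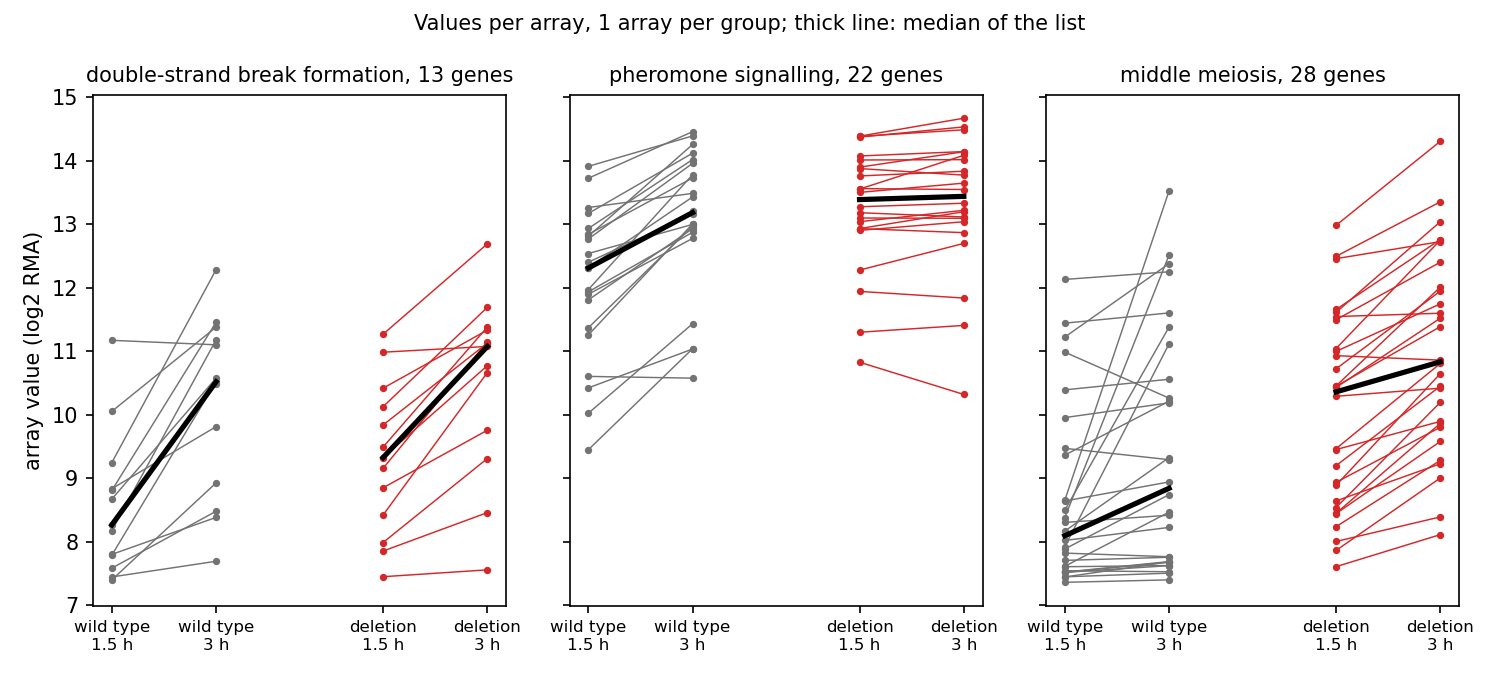
Array values (log2 RMA) of the double-strand break, pheromone and middle meiosis lists on the 4 arrays, 1 line per gene, with the median of all members as the thick line. The break list median is 8.26 and 10.52 in wild type at 1.5 h and 3 h and 9.32 and 11.07 in the deletion, and the middle meiosis median is 8.09 and 8.84 against 10.36 and 10.83.

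The change with time differed between the genotypes by 2-fold or more for 55 of 2400 genes, given here as the change in the deletion minus that in wild type, which was positive for 12 and negative for 43. Most negative were isp3 (-4.65), spo5 (-3.55), crs1 (-2.43) and mug14 (-2.33), which were higher at 3 h in both genotypes and by less in the deletion, and ctr4 (-2.27), which went by -0.09 in wild type and by -2.36 in the deletion. Most positive were spn5 (1.65), mug137 (1.35), mde2 (1.35) and meu25 (1.15), with the larger change in the deletion, and frp2 (1.28), which went by -1.74 in wild type and by -0.46 in the deletion. The wild-type values of isp3, spn5, mug137, mde2 and meu25 at 1.5 h lay under 8.37, so their sizes are uncertain. In the deletion at 3 h, isp3 (14.51), mug14 (14.57) and spo5 (14.31) read near the highest value of that array (14.88), and crs1 read 12.75. Whether this limited their rise was not tested. The pheromone list had a median difference of change of -0.94 with 22 of 22 genes negative, 8 by 2-fold or more, and core histones one of 0.32 with 10 of 10 positive. With 1 array per group this difference was not tested.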

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

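All tests in this part were chosen after the results were seen, including the split of the early genes by list. Their bootstrap intervals are over genes, which can move together, and do not measure the spread between arrays or cultures. The genes and lists given first were picked out because they moved in opposite directions at the 2 times or in the 2 genotypes, and these differences were not tested. Between genotypes, the copper transporter genes ctr4 (0.85 at 1.5 h, -1.42 at 3 h) and ctr5 (0.50 and -0.80) were higher, then lower, in the deletion, as was the ribosomal protein gene rps1401 (0.51 and -0.99). The spore wall glucanase gene agn2 went from 1.5 h to 3 h by -0.50 in wild type and by 0.63 in the deletion. The metal and phosphate uptake list had a median of -0.21 at 1.5 h and 0.12 at 3 h. Among probe sets outside the named genes, 12 were at least 2-fold higher and 8 at least 2-fold lower in the deletion at both times. A probe set shared by meu1-1 and meu1-2 was higher by 2.14 at 1.5 h and 0.90 at 3 h, and one shared by wtf13 and wtf18 by 0.87 and 1.21.

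Middle meiosis genes were higher in the deletion at both times. If the whole deletion culture ran ahead of wild type by less than 1.5 h, its values at 1.5 h should not exceed those of wild type at 3 h, provided that wild type does not peak in between. Yet 23 of 28 genes exceeded them, with a median of 0.48 (95% bootstrap interval over genes 0.19 to 0.72). Scaling or an intensity trend is argued against by a median of 1.21 at 3 h after its removal, above all random lists at both times. What stays open is an effect of the genotype itself, untested beyond 1 sample per genotype and time. A share of cells further on or already past meiosis, whose own profile was not measured, also stays open. The linear excess grew by 1.29 log2 units (0.96 to 1.61 over 26 genes with an excess at both times), which excludes neither. A whole-culture lead of 1.5 h or more was not addressed by this test. It would put the deletion at 1.5 h at a stage no earlier than wild type at 3 h. Yet none of the 13 double-strand break genes in the deletion at 1.5 h exceeded wild type at 3 h. Their median lay at -0.96 (-1.16 to -0.53 over genes), and all 13 were higher by some amount at 3 h in the deletion. For these genes this argues against such a lead, provided that they do not fall and rise again.

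Early meiosis and pheromone genes were higher in the deletion at 1.5 h. Over the 46 genes of the double-strand break, pheromone and meiotic entry lists together, the deletion at 1.5 h lay at -0.091 (-0.20 to 0.07) against wild type at 3 h, so a whole-culture lead under 1.5 h and a genotype effect cannot be told apart on these lists. Split by list, the 13 break genes lay at -0.96 (-1.16 to -0.53), none above wild type at 3 h. Such a lead would give this, but so would no lead, since these genes mostly rose with time in wild type. This position alone therefore does not decide. The 22 pheromone genes lay at 0.11 (-0.04 to 0.21), which leaves them open. An unequal start of nitrogen withdrawal could not be judged, because the 20 nitrogen starvation genes themselves moved with time in wild type by a median of only -0.079. The genotype effect also stays open and untested.

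Of the 27 genes called lower over both times, 26 were other than pht1, among them usp109, sgf73, arp9 and swc5. A difference in meiotic timing should show in these genes as a fall with time, but their median time effect was -0.045 (-0.15 to 0.01 over genes). Single genes ranged from aes1 (-1.02) to sgf73 (0.30). The fit favours genes with a like difference at both times, which limits this test. Removing the intensity trend left their median difference at -0.97, or 97.2% of its size before, which argues against scaling. A genotype effect and a difference between the strains or cultures other than pht1 stay open and untested.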

How the results depend on the processing

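No named difference of 2-fold or more changed direction under the alternatives run, and 630 of 630 values moved by less than the spread between arrays. Smaller differences were not checked for direction. The genes in this check have 1 probe set each, so the choice of probe sets could not move them. Of 55 alternative counts, 41 stayed within 1.5 times the value in the report. A 1.5-fold threshold gave 218 and 151 genes between genotypes at 1.5 h and 3 h, 180 and 137 with time in wild type and the deletion, and 126 for the difference of changes. A 3-fold threshold gave 33, 27, 39, 18 and 13 in the same order. The stricter floor at the array median gave 49 and 40 between genotypes and 40 with time in the deletion, from fewer genes. Counting all probe sets, an alternative chosen after seeing the data, gave 107 at 3 h. The additive fit called 31 genes without the intensity trend in the variances, 141 with robust variances, 166 after quantile normalization, 215 after lowess, 106 with no floor, 1 with the stricter floor and 132 with a floor set after seeing the data, 1 unit above the deleted gene. Of the 49 genes, 28 stayed called without the trend. With the stricter floor 1 of the 32 still tested stayed called, a higher gene, so pht1 was missed although its wild-type values lay above that floor. All 49 stayed called in the others, and the signs were the same throughout. The cause of these shifts in the calls was not tested. Of 480 list medians under alternatives, 456 kept their side, 14 moved outside the random range and 10 into it or lost their percentile. With the stricter floor, the strand exchange, bouquet and Mmi1 lists had 4 genes left at 1.5 h and no percentile, and those of nitrogen starvation (-0.10) and metal and phosphate uptake (-0.080) moved inside, nitrogen starvation also after quantile normalization (-0.12). At 3 h it moved strand exchange (0.24), meiotic entry (0.14), Mmi1 (0.34) and other chromatin factors (-0.032) inside. The double-strand break list moved outside with no floor (0.84 at 1.5 h, 0.23 at 3 h) and with the floor from the deleted gene (1.11 and 0.26). So did the cohesin and linear element list (0.51 and 0.23 with no floor) and, at 3 h, the bouquet list (0.15) and the respiration list (-0.06, below). Scaling moved the median of all genes by at most 0.04. Signal over background limits dim genes such as rec7 and rec24, which stayed under the floor on all 4 arrays. No leave-one-out was possible with 1 array per group. The additive fit compares the genotypes within each time, and no other pairing of arrays is given by the labels.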

Other observations

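The list of genes on subtelomeric clones of chromosomes I and II had a median of 0.34 over 11 genes at 1.5 h and 0.35 over 10 at 3 h in the deletion against wild type, with 7 of 11 and 7 of 10 higher, 4 and 2 of them at least 2-fold. The alpha-galactosidase gene mel1 was higher by 2.01 and 1.50 at the 2 times, its neighbour pcm2 by 1.45 and at least 1.22, gal10 by 1.48 and 1.47 and say1 by 0.96 and 1.06. On the same clones put4 (-0.21 and -0.65), aat1 (-0.72 and -0.45), abc3 (-0.44 and -0.19) and nhe1 (-0.021 and -0.34) were lower at both times, and cat1 at 1.5 h (-0.30). Sugar uptake genes stood out singly, with ght6 at 3.12 or more and 3.85 or more and ght3 at 1.43 and 0.85. In wild type, the succinate dehydrogenase genes sdh2 (2.34) and sdh3 (1.28) and the cytochrome genes cyc1 (1.25) and cyt1 (1.07) were higher at 3 h than at 1.5 h.

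A hypothesis chosen after the values were seen is that position near chromosome ends goes with higher levels in the deletion. The list median lay above nearly all matched random lists at both times, the lower of its percentiles being 99.99, but this value raised the hypothesis and cannot test it. Without members of the meiotic lists it was 0.26 over 10 genes at 1.5 h and 0.37 over 9 at 3 h. Members differed in both directions, the list is short and coordinates were not used, so the hypothesis stays open.

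Arrays can be parted into pairs in other ways, also examined after the results were seen. The diagonal parting sets wild type at 3 h and the deletion at 1.5 h against the other arrays. Its fit leaves the genotype difference in the residual, so a low count is built in and is no check of the genotype calls. The fit by limma called 49 genes for genotype with 615 at an unadjusted p under 0.05, 0 for time with 527 at that level, and 0 for the diagonal parting with 12. Over all probe sets, the deletion at 1.5 h correlated with wild type at 3 h at r = 0.972 and with wild type at 1.5 h at r = 0.964, while wild type at 1.5 h and the deletion at 3 h were farthest apart at r = 0.928.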
